A study of Homo sapiens with 24 samples.

How the data were processed

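Input RNA and ribosome footprints were sequenced from A549 and H1299 cells, both established lung cancer lines, with stable CRISPR-Cas9 knockout of METTL5 or a control guide. Per the labels, 24 libraries fell into 8 groups by line, kind of library and genotype, with 2 control and 4 knockout libraries in each. The labels' protocols state that cells were given fresh medium for 2 h and cycloheximide for 5 min, that footprints were made with RNase I and selected at 30 nt, and that input RNA was fragmented chemically and selected at 40 to 60 nt. A549 cells grew in DMEM and H1299 cells in RPMI medium, so the lines differ in medium too. The guides, the site they target and the clones behind the numbered libraries are not given in the sources used here.

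The authors deposited 1 table of raw read counts per gene for all libraries, and the counts were used as deposited. The submitters' processing notes name cutadapt 2.8, Bowtie2 2.2.5, HISAT2 2.2.1, featureCounts 2.0.1, edgeR 4.8.0 and the genome build GRCh38, without their roles. The annotation release, the strand setting and the treatment of reads with several matches or of PCR duplicates are not given in the sources used here. Intervals and floors below therefore cover counting error only, and genes with near-identical copies or overlapping neighbours are uncertain. The table holds 19994 protein-coding genes, of which 629 have no name and 8 names stand on more than 1 gene; 19948 identifiers were found in the reference gene table. All columns of values matched a labelled sample. The 28 pairs of replicates had a chi-square per degree of freedom of 1.33 to 15.6, so none was an exact copy and each library was counted once. This does not show that they are independent: knockouts 3 and 4 were the closest or next closest pair of each set (1.53 and 1.71 in A549 and H1299 RNA, 2.20 and 1.58 in footprints), and in A549 RNA knockouts 1 and 2 stood at 1.33.

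Depth differed between sets. Totals were 716012 to 911099 in A549 control RNA, 723961 to 1385263 in A549 knockout RNA, 1158992 to 1909768 in H1299 control RNA and 641979 to 1296596 in H1299 knockout RNA. In footprints they were 233355 to 380823 and 214882 to 697826 in A549 controls and knockouts, and 839426 to 925102 and 1171261 to 1850663 in H1299. The A549 footprints are thus the shallowest set, and H1299 knockout footprints are all deeper than their controls.

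Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, filterByExpr) and Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. RNA and footprints were each fitted over their 12 libraries with group means (8 residual degrees of freedom, biological coefficient of variation 0.235 and 0.181), so that the spread was shared by both lines. Translational efficiency was the interaction of kind of library and genotype in 1 model over all 24 libraries (16 residual degrees of freedom, 0.211). The line difference was the knockout effect in A549 minus that in H1299. Log2 changes are knockout minus control with their standard errors, fold changes come from them, and CPM of genes other than METTL5 is per raw library total. For METTL5 and for the share of counts in the 13 mtDNA-encoded genes, log2 values were compared by 2-sided exact permutation tests that reassigned genotypes within each line, with Benjamini-Hochberg adjustment over 10 tests. For a group with 0 counts the fold is a bound against 3 counts over the whole group, and for 1 to 3 counts the ratio is given with its 95% exact counting interval.

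Before the data were examined, 39 gene lists with 1061 entries were written from textbook knowledge, of which 1058 matched the table. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation of 0.01 between genes), adjusted over 210 tests in the 6 comparisons. Marker lists of alveolar and airway epithelium, blood and immune cells, endothelium and fibroblasts had fewer and were not tested. Of the 33 list calls, 0 held with an estimated correlation and 0 with fry, with smallest adjusted p of 0.337 and 0.115. Counts of called members are over all genes tested, and those adjusted over the list alone are named as such.

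The genes named follow a rule fixed before the data were examined: METTL5 and the mtDNA-encoded genes, and per comparison up to 8 called genes with the largest rise and 8 with the largest fall. These needed a mean of at least 5 CPM and every knockout library on the same side of both controls. To these were added up to 4 called members of each called list (or, with 0 called, the 2 with the smallest p), genes called in both lines and up to 6 with a line difference. Exceptions are named as chosen after their values were seen. Results of 2 genes that the rule took are not reported here.

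The same steps were tested on simulated counts with 200 changed genes in A549, after exploratory fits of the data had been made. In A549 RNA (10429 genes) 75.0% of genes lowered by a log2 change of -2 and 96.0% of those raised by 2 were recovered, against 16.3% and 42.0% at -1 and 1. In A549 footprints (9777 genes) the shares were 54.2% and 88.0%, and 17.4% and 12%. In A549 efficiency (9408 genes) they were 44.0% and 48.9%, and 6.38% and 2.00%. False calls made up 2.59%, 2.33% and 5.77% of calls. The simulated libraries were independent, had the same spread for all genes and did not separate by number as the real ones do. These shares hold for that setting and are no error rates of the real calls.

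Alternatives fixed beforehand were DESeq2 1.42.0, limma voom, RLE size factors, library totals as the scaling, no low-count filter, a filter at a mean of 5 CPM, each line fitted alone, the replicate number as a block, a term for libraries whose label gives a library name, mtDNA-encoded genes left out before scaling, a minimum absolute log2 change of 1 and each library left out in turn. The labels give a library name for control 1 and knockout 2 of each line and kind of library. Added after the data were seen were a term for the separation of the libraries by number, fits without A549 knockouts 3 and 4 or without A549 control 1 and knockout 1, list tests of the line difference, list tests with mtDNA-encoded genes left out, knockouts 1 and 2 and knockouts 3 and 4 summed (or, for permutation tests, averaged) into 1 replicate each, permutations within the sides of that separation, and a permutation of the ratio with RNA and footprint libraries not matched by number. Also added was a straight line of the mtDNA-encoded share on the share of MTRNR2L counts over the footprint libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the permutation tests and figures.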

Results

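Ribosome footprints and input RNA were sequenced from 2 human non-small cell lung cancer cell lines, A549 and H1299, carrying either a control guide or a CRISPR-Cas9 knockout of METTL5. METTL5 is the m6A methyltransferase of the small-subunit ribosomal RNA. A footprint is the stretch of messenger RNA that a translating ribosome shields from nuclease. Its count is read here as how much a gene is translated, and the input RNA count as its transcript level. Whether cycloheximide and the selected footprint size captured mitochondrial ribosomes was not tested. Reading footprints as translation is therefore uncertain for genes encoded by mitochondrial DNA. Each line had 2 control and 4 knockout libraries of each kind, 24 libraries in 8 groups. Total gene counts ran from 641979 to 1909768 in the RNA libraries. They ran from 214882 to 697826 in the A549 footprint libraries and from 839426 to 1850663 in the H1299 footprint libraries. The labels number the libraries of a group but do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. In A549 RNA, knockouts 1 and 2 and knockouts 3 and 4 lay close together (chi-square per degree of freedom 1.33 and 1.53) against 14.7 to 15.6 across these pairs. The 4 knockouts may therefore hold fewer independent samples, and each count of calls is also given with both pairs summed, a choice made after seeing the data. In H1299 RNA the knockout pairs stood at 1.71 to 5.4. The edgeR fits share the spread of a gene between the lines, so edgeR p-values for A549 do not measure the A549 spread alone. Fitted alone, with fewer libraries, A549 RNA gave 0 called genes against 37, and H1299 RNA 224 against 48.

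METTL5 (chromosome 2, 169811757 to 169824905, GRCh38) was read first, because its level bears on the labels. In H1299 RNA it was counted 26 and 27 times in the control libraries and 9, 5, 10 and 5 times in knockouts 1 to 4. After TMM scaling this gave 18.02 ± 5.00 CPM (counts relative to the library total; SD, n = 2) and 7.16 ± 1.16 CPM (n = 4). In A549 RNA the counts were 13 and 15 in controls and 7, 12, 11 and 10 in knockouts, or 17.7 ± 3.37 CPM and 11.1 ± 4.20 CPM. Over both lines the METTL5 transcript fell by 1.02 on the log2 scale, a 2.03-fold lower level (2-sided exact permutation test within lines, p = 0.00889, adjusted p = 0.0296 over a family of 10 tests). With the knockouts averaged in pairs the exact permutation p was 0.0556, the smallest of 36 arrangements. In footprints it was 27.9 ± 12.2 CPM in H1299 controls (32 and 18 counts) and 9.97 ± 4.15 CPM in knockouts (10, 21, 20 and 11 counts). The A549 footprint libraries held 1 and 6 counts in controls and 1, 6, 7 and 7 in knockouts, and the levels of 10.4 ± 8.13 CPM and 11.1 ± 4.27 CPM differed by less than the spread between replicates. The mean footprint change over both lines was -0.63 (exact permutation p = 0.258). edgeR called METTL5 in H1299 footprints alone (log2 change -1.49, adjusted p = 0.0453). That call was lost in 5 of the 6 fits that left out 1 H1299 library, where the change ranged from -1.901 to -0.98. A guide can disrupt the protein and leave the transcript in place, and the knockout 2 library of A549 RNA, at 17.3 CPM, lay within the control range of 15.3 to 20.04 CPM, so in A549 the METTL5 level does not check the labels.

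**Figure D1:**
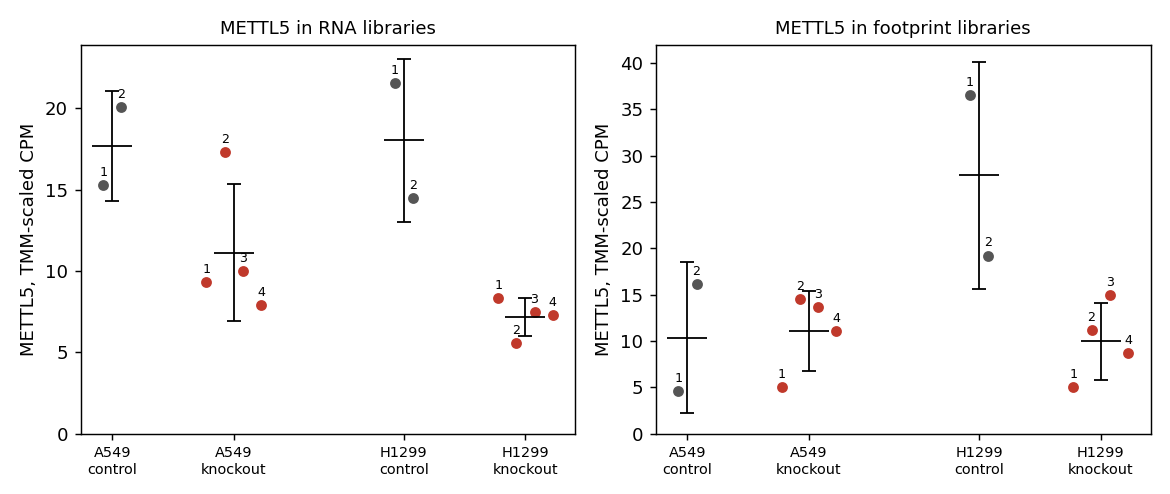
METTL5 in each library, in CPM after TMM scaling, for RNA (left) and footprints (right); points are libraries with their number in the labels, horizontal lines are group means and bars 1 SD (n = 2 controls and n = 4 knockouts per line). All 4 H1299 knockout RNA libraries sit between 5.57 and 8.35 CPM, under both controls at 14.5 and 21.6 CPM, while A549 knockouts and controls overlap.

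The series asks whether loss of METTL5 lowers translation inside mitochondria, which make the 13 proteins encoded by mitochondrial DNA (mtDNA), all of them subunits of the respiratory chain or of ATP synthase. In H1299 these 13 genes took 5.81% ± 3.26 (SD, n = 2) of footprint counts in controls and 0.709% ± 0.137 (n = 4) in knockouts, with every knockout library under both controls. In A549 the share lay the other way, 1.13% ± 0.0332 (n = 2) in controls and 4.802% ± 2.78 (n = 4) in knockouts, with every knockout library above both controls. The share in RNA differed less: 10.2% ± 4.63 and 7.21% ± 1.60 in H1299, and 6.39% ± 1.09 and 10.8% ± 5.26 in A549. Each footprint share was also set against the RNA share of the same number, though the numbers were not taken to pair the samples. The footprint share was 0.553 ± 0.0687 of the RNA share in H1299 controls and 0.0996 ± 0.0133 in knockouts, a 5.57-fold lower ratio. In A549 it was 0.180 ± 0.0359 and 0.434 ± 0.107, a 2.38-fold higher ratio. The lines differed in the footprint share (log2 difference 4.8, A549 minus H1299) and in the ratio (3.73), each with p = 0.00444 in the 2-sided exact permutation test, the smallest p that test can give (adjusted p = 0.0222). The ratio difference is that of footprints less that of RNA and does not depend on how libraries are matched, but its p does. With genotypes reassigned in RNA and footprints independently, a test chosen after seeing the data, the exact permutation p was 0.0404 (50625 arrangements). For RNA the line difference was 1.07 (exact p = 0.133). Counts of the MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA, moved the same way as the mtDNA-encoded share. They went from 0.908% ± 0.157 (n = 2) to 2.01% ± 0.759 (n = 4) of A549 footprint counts and from 2.57% ± 0.820 to 0.907% ± 0.154 in H1299. With the knockouts averaged in pairs, the line differences of the mtDNA-encoded footprint share and of the ratio had an exact p = 0.0556, the smallest of 36 arrangements. In each set the split of control 1 with knockouts 1 and 2 from control 2 with knockouts 3 and 4 took more of the variance within groups than the other 5 splits, 64.8% against at most 20.9% in A549 RNA, and 31.6% to 32.2% against at most 25.9% to 27.4% in the other sets. Within the first side the line differences were 3.63 in footprints and 3.27 in the ratio, and within the second 5.97 and 4.19, each with an exact p = 0.111, the smallest that 9 arrangements can give. Over both sides, genotypes were also reassigned within each, a test chosen after seeing the data. The line differences in footprints (4.8), the ratio (3.73) and RNA (1.07) each had an exact permutation p = 0.0123, the smallest of 81 arrangements. These arrangements count both knockouts of a side as separate samples, which they may not be, and the test was not run with them averaged. For RNA the exact permutation p without this restriction was 0.133. No mean change over both lines passed (exact p = 0.582 for footprints, 0.382 for the ratio and 0.8 for RNA). A single line has 15 arrangements, whose smallest 2-sided p of 0.0667 cannot pass.

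**Figure D2:**
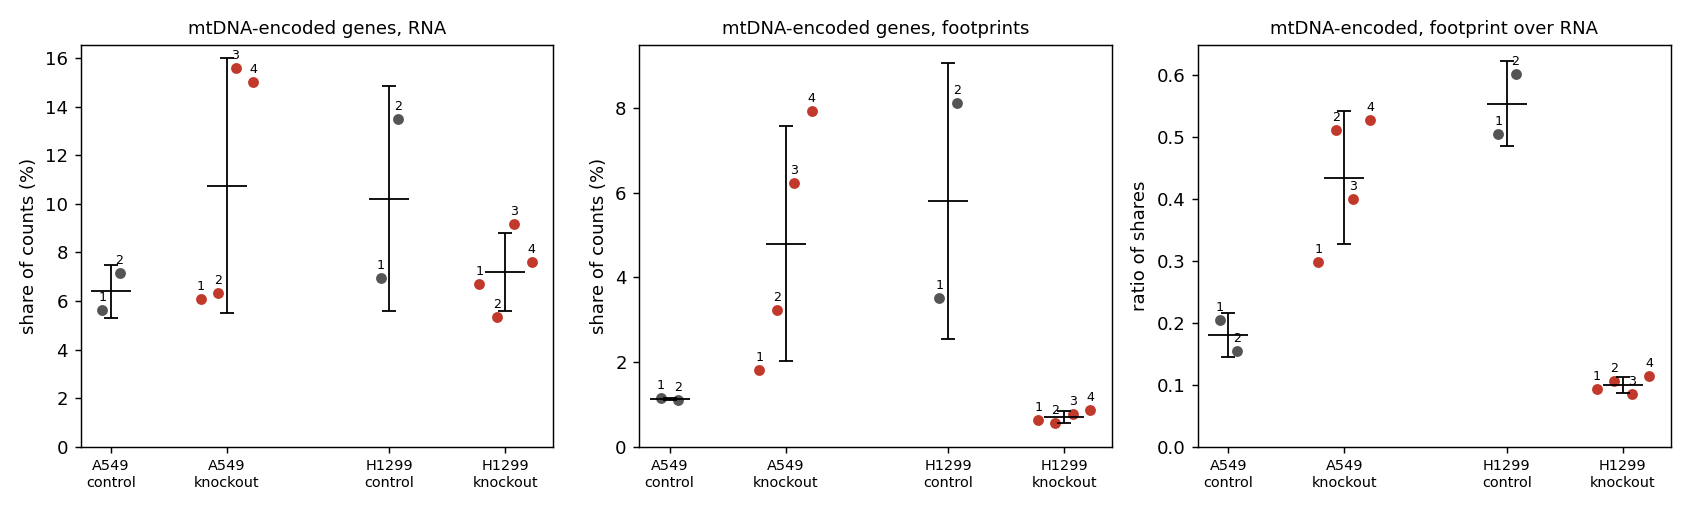
Share of gene counts in the 13 mtDNA-encoded genes in each RNA library (left, %) and footprint library (middle, %), and the ratio of the footprint to the RNA share of the same number (right, no unit); points are libraries with their number, lines group means and bars 1 SD (n = 2 and n = 4). The footprint shares of the H1299 knockouts, 0.571% to 0.868%, lie under both H1299 controls, and those of the A549 knockouts, 1.81% to 7.92%, lie above both A549 controls.

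Gene by gene, all 13 mtDNA-encoded genes had negative footprint estimates in the H1299 knockout (median log2 change -3.005), and 6 were called lower by edgeR. MT-CO1, the catalytic core of cytochrome c oxidase, fell by 3.38 ± 0.62 (SE) on the log2 scale, 10.4-fold (adjusted p = 0.0377). The complex I subunits MT-ND5 (-3.36), MT-ND4L (-3.24), MT-ND4 (-2.96 ± 0.36, adjusted p = 0.000721) and MT-ND2 (-2.89) fell with it, as did MT-CYB, the cytochrome b of complex III (-3.16 ± 0.45, adjusted p = 0.00949). Adjusted over the list alone, all 13 passed. Estimates of the other 7 genes ran from -3.16 for MT-CO3 to -2.37 for MT-ND1. In A549 footprints all 13 estimates were positive (median 2.30) with 0 called by edgeR over all genes and 12 adjusted over the list alone; MT-ND4 came nearest (2.002 ± 0.41, adjusted p = 0.0971). The competitive test camera called the list in both lines (adjusted p = 1.9e-25 lower in H1299 and 3.37e-15 higher in A549), but not with a correlation between genes estimated from the data (adjusted p = 0.337 with an estimated correlation in H1299 and 0.812 in A549). In RNA the list was called lower in H1299 (median -0.46, camera adjusted p = 0.0139; adjusted p = 0.962 with an estimated correlation) and higher in A549 (median 0.91, 1.35e-06; 0.962), with 0 members called and 0 adjusted over the list alone in either line. The A549 RNA estimate goes with knockouts 3 and 4, whose RNA libraries held 15.6% and 15.0% mtDNA-encoded counts: without them its median was 0.03 (camera adjusted p = 0.923). Without H1299 control 2 the H1299 RNA median turned to 0.12 (adjusted p = 0.838), and without H1299 knockout 2 it was -0.37 (adjusted p = 0.173). MT-ND4 and MT-CYB stayed called in H1299 footprints whichever H1299 library was left out, at -2.24 and -2.48 without control 2. MT-CO1, MT-ND5 and MT-ND4L lost their call in each of the 6 such fits and MT-ND2 in the 5 other than that without control 1, with changes between -3.88 and -1.96. With knockouts summed in pairs MT-ND2 (adjusted p = 0.165) and MT-ND4L (0.265) were lost, and MT-CO3 (0.0207) and MT-ND3 (0.0245) were called. MT-ATP8 overlaps MT-ATP6, and MT-ND4L overlaps MT-ND4, so reads of each pair may be shared.

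**Figure D3:**
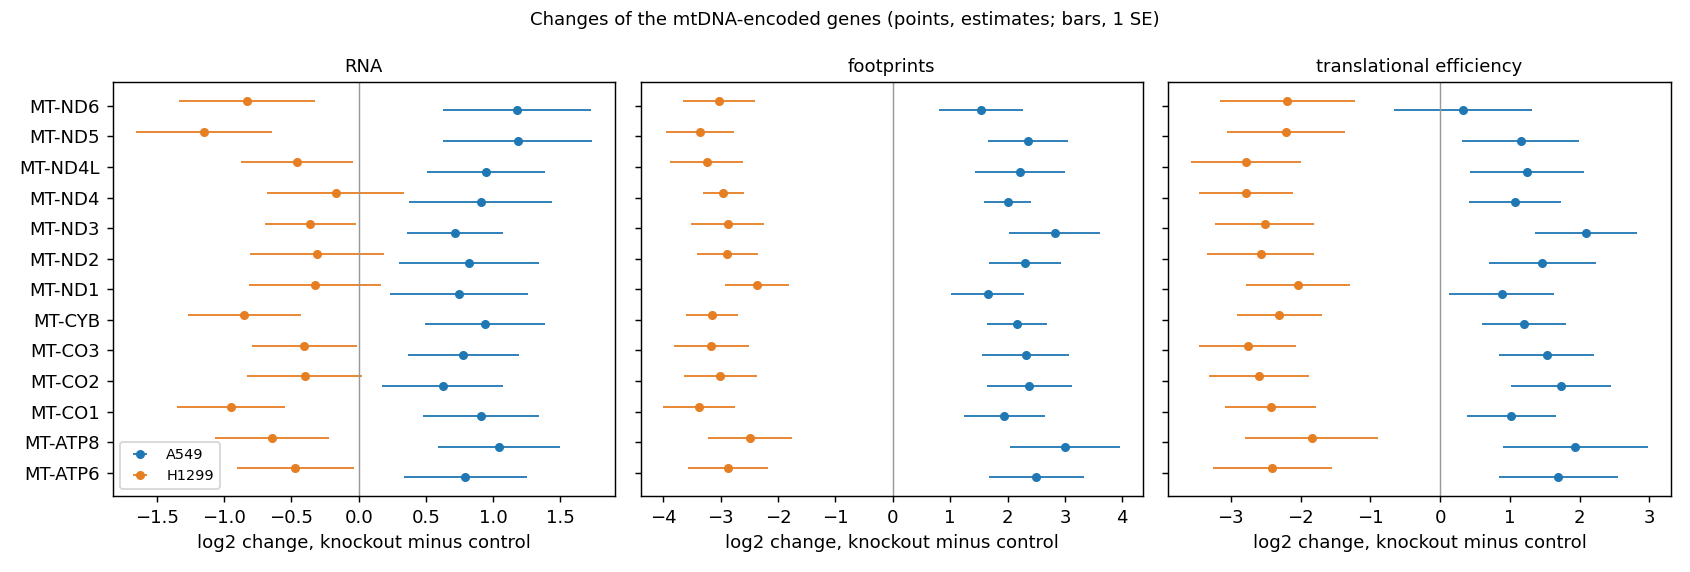
Log2 change (knockout minus control) of each mtDNA-encoded gene in RNA, footprints and translational efficiency, in A549 (blue) and H1299 (orange); points are edgeR estimates and bars 1 SE. Footprint estimates run from 1.54 to 3.002 in A549 and from -3.38 to -2.37 in H1299, of which 6 in H1299 passed the adjusted threshold.

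Translational efficiency is the footprint change beyond the RNA change, tested for each gene in 1 model over both kinds of library. For the mtDNA-encoded genes it compares counts and is no measured rate of mitochondrial translation. In H1299 the 13 mtDNA-encoded genes had a median efficiency change of -2.43, from -2.78 for MT-ND4 to -1.84 for MT-ATP8, and 12 passed when adjusted over the list alone. In A549 all 13 estimates were positive with a median of 1.25, the highest MT-ND3 (2.10 ± 0.74), and 0 passed over the list alone. camera called both (adjusted p = 1.66e-31 and 3.84e-09), which did not hold (adjusted p = 0.337 and 0.879 with an estimated correlation). A549 histones were called higher by camera, with all 50 estimates positive, 0 called and 0 over the list alone (median 0.50, adjusted p = 4.33e-09; adjusted p = 0.962 with an estimated correlation; H2BC18 1.42, H2AC16 1.11). Nuclear-encoded complex I genes were called higher too, 25 of 34 positive, 0 called and 0 over the list alone (0.26, 0.0298; 0.962 with an estimated correlation; NDUFC1 1.27, NDUFB6 1.12). In H1299 the NF-kB and cytokine list was called lower (9 of 15 negative, 0 called, 1 over the list alone, median -0.18, 0.0314; 0.879 with an estimated correlation; CXCL3 -1.92, CXCL2 -1.15). Over all 9450 genes edgeR called 0 genes in A549, 0 in H1299 and 0 for the line difference, with 356, 248 and 417 at an unadjusted p under 0.05. Each of these 3 counts is under the share of 0.05 of tested genes that chance alone gives at that threshold. DESeq2 called 0, 0 and 9, limma voom 0, 0 and 0, and the fit with no low-count filter 3, 15 and 20, of which 2, 13 and 13 were mtDNA-encoded. Without A549 control 1 the histone median was 0.12 (camera adjusted p = 0.348) and that of complex I turned to -0.01 (0.866), and without knockouts 3 and 4 they were 0.08 (0.979) and 0.05 (0.95). Complex I was also lost without knockout 3 alone (0.19, 0.239) or knockout 4 alone (0.16, 0.231), and the NF-kB list was lost without H1299 control 1 (-0.45, 0.0946), control 2 (median 0, 0.181), knockout 3 (-0.05, 0.0583) or knockout 4 (-0.20, 0.0736), and with knockouts summed in pairs (-0.23, 0.05). For the line difference in efficiency, leaving out A549 knockout 1 gave 11 genes, 6 of them mtDNA-encoded.

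In A549 RNA, SPARC and the collagen chains COL6A2, COL6A1 and COL5A1 rose in the METTL5 knockout, and TM4SF4, FOXA1 and MUC5B fell. SPARC, a collagen-binding matrix protein, rose 16.9-fold in RNA, from 4.84 ± 0.918 CPM (n = 2) to 79.4 ± 26.6 CPM (n = 4, log2 4.08 ± 0.60, edgeR adjusted p = 0.00334). The collagen VI chains COL6A2 (7.17-fold, adjusted p = 0.00312) and COL6A1 (6.37-fold, 0.00312) and the collagen V chain COL5A1 (3.52-fold, 0.0447) rose with it. Of the mesenchymal markers, 4 of 20 were called higher and 6 passed over the list alone (median 0.57, camera adjusted p = 1.26e-11; adjusted p = 0.337 with an estimated correlation). Among the largest falls were TM4SF4, a tetraspanin-like membrane protein (8.28-fold, from 129 ± 16.4 to 15.9 ± 8.90 CPM, adjusted p = 0.00334), FOXA1, a transcription factor of airway epithelium (7.13-fold, 0.0235), and the airway mucin MUC5B (5.33-fold, 0.00475).

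Further A549 RNA rises were GFRA1, a GDNF-family receptor (9.03-fold, edgeR adjusted p = 0.00628), and NPTX1 (6.94-fold, 0.00628). The controls held 3 counts each of EDIL3 and ITGB3, integrin beta 3, giving count ratios of 20.2 (95% counting interval 6.78 to 98.9) and 12.3 (4.10 to 61.0). LRIG1, with 0 counts in both controls and 43 in the knockouts, was at least 5.4-fold higher against a floor of 3 counts over the group. Falls also took NKD1 (13.2-fold, adjusted p = 0.0442), SHROOM3 (5.54-fold, 0.0192), the receptor kinase NTRK3 (4.86-fold, 0.00334), the glutathione peroxidase GPX2 (3.88-fold, 0.0181) and DOK4 (3.74-fold, 0.0300). Epithelial markers were called lower as a list (7 of 9 negative, 0 called and 0 over the list alone, median -0.58, camera adjusted p = 0.00579; 0.337 with an estimated correlation; KRT19 -2.08, ELF3 -0.75). NRF2 targets were called lower as well (21 of 26 negative, 0 called, 0 over the list alone, median -0.30, 0.000721; 0.395 with an estimated correlation; AKR1C1 -1.02, HMOX1 -0.81). Smaller list calls, each with 0 members called and 0 over the list alone, were ER chaperones (18 of 22 positive, median 0.38, 0.0139; HYOU1 0.64, ATF6 0.64) and cholesterol synthesis (17 of 24 positive, 0.26, 0.0482; SQLE 1.00, SC5D 1.39) higher. Histones (47 of 50 negative, -0.40, 2.2e-06; H2BC7 -0.73, H4C8 -0.63) and the large ribosomal subunit (41 of 47 negative, -0.16, 0.0398; RPL21 -0.77, RPL19 -0.33) were called lower. These 4 were not called with an estimated correlation (adjusted p = 0.962, 0.962, 0.962 and 0.981).

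edgeR called 26 genes higher and 11 lower among 10490 in A549 RNA (DESeq2 51, limma voom 40, A549 libraries fitted alone 0). The count moved to 11 higher and 10 lower without control 1, to 0 higher and 3 lower without control 2, and to 23 without knockout 3 and 18 without knockout 4. It was 3 with knockouts summed in pairs, namely SPARC, COL6A1 and COL6A2. The log2 change of COL5A1 was 2.67 without control 1 and that of SHROOM3 -1.87 without control 2. Of the 17 named A549 RNA calls, only TM4SF4 and NTRK3 held in all 6 of the fits with 1 library left out. Without control 2, 15 were lost. Without control 1 the epithelial list (adjusted p = 0.0717) and the ER chaperones (0.162) lost their call, and the medians of histones (0.16) and the large ribosomal subunit (0.22) turned positive. Knockouts 3 and 4 stood apart from knockouts 1 and 2 in A549 RNA. Without both, the count was 25, while histones (0.14, adjusted p = 0.0157), the large ribosomal subunit (0.12) and ER chaperones (-0.02) turned their direction and cholesterol synthesis was no longer called (0.201). Cholesterol synthesis was also lost without control 2, knockout 2, knockout 3 or knockout 4 (0.6, 0.0579, 0.0617 and 0.0579) and with library totals as the scaling (0.0611). ER chaperones were lost without knockout 3 (0.0621) or 4 (0.125), and the large ribosomal subunit without knockout 3 (0.573) or 4 (0.581) with RLE scaling (0.0508) and with knockouts summed in pairs (0.077). Histones belong to multigene families whose reads can be shared between copies.

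In A549 footprints COL6A2 rose 5.37-fold (12.2 ± 5.08 to 63.5 ± 23.2 CPM, edgeR adjusted p = 0.0144), COL6A1 4.51-fold (0.0162) and SPARC from 2 counts in both controls to 125 in the knockouts (ratio 19.9, 95% counting interval 5.41 to 166). The secreted follistatin-like protein FSTL1 rose from 4 counts, all in control 2, to 104 (edgeR adjusted p = 0.0144). Its log2 change of 3.09 was 2.49 without control 1. Without control 2 no control count of FSTL1 was left, so the fitted 8.79 is neither a measured change nor a bound. Also higher were the WNT antagonist SFRP1, 5.27-fold (0.0144), the vesicle GTPase RAB3B 3.86-fold (0.0251) and FSTL4 3.59-fold (0.0144). SLC1A3, a glutamate transporter, had 0 counts in controls and 73 in knockouts, at least 6.63-fold higher. NFIB, a lung transcription factor, was the only call among falls (6.25-fold, 0.0393). Without control 2 the log2 changes of COL6A2, SFRP1 and NFIB were 3.02, 1.499 and -1.56, and without control 1 that of SFRP1 was 3.69. Mesenchymal markers were called higher (19 of 20 positive, 3 called, 5 over the list alone, median 1.10, camera adjusted p = 4.97e-10; 0.337 with an estimated correlation).

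Ribosomal protein lists were called lower in A549 footprints by small medians: 35 of 47 large-subunit genes (median -0.15, camera adjusted p = 0.0346, 0 called, 1 over the list alone; RPL39 -1.23, RPL24 -0.69), 26 of 33 small-subunit genes (-0.21, 0.0314, 0 called, 0 over the list alone; RPS29 -0.62, RPS21 0.67) and 36 of 48 mitoribosomal large-subunit genes (-0.20, 0.0314, 0 called, 0 over the list alone; MRPL41 -0.66, MRPL27 -0.54). None of the 3 was called with an estimated correlation (adjusted p = 0.962 each). Without A549 control 1, the second shallowest library, their medians were 0.07, 0.02 and -0.01 (0.961, 0.706 and 0.578). Without knockout 3 the large (0.143) and small (0.117) subunits were lost, without knockout 4 all 3 (0.173, 0.157 and 0.0894), and without knockout 1 the mitoribosome (0.0985). All 3 were lost with knockouts summed in pairs (0.0828, 0.112 and 0.0605). edgeR called 10 genes higher and 1 lower among 9779 (8 higher and 2 lower with library totals as the scaling, 6 higher and 15 lower with limma voom, 42 in all with DESeq2). Of these 11 calls, DESeq2 shared 6, limma voom 5 and the A549 libraries fitted alone 4 (of 9 calls). With knockouts summed in pairs edgeR called 4 higher, SPARC, COL6A2, SFRP1 and FSTL4, and 2 lower. The count was 41 without control 1, 1 without control 2 (0 higher and 1 lower), 161 without knockout 1 (the shallowest library), 1 without knockout 2, 1 without knockout 3 and 11 without knockout 4. None of the 9 named nuclear calls held in all 6 of these fits.

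In H1299, METTL5 knockout was accompanied by near-complete loss of a few transcripts. MYO10, an unconventional myosin of filopodia, had 151 RNA counts in the 2 controls and 2 in the 4 knockouts (ratio 0.0105, 95% counting interval 0.00127 to 0.0387; edgeR adjusted p = 7.87e-05) and 53 against 0 in footprints, at least 60.6-fold lower. The guidance ligand SLIT3 fell 25.6-fold in RNA (42.4 ± 5.92 to 1.84 ± 1.71 CPM, adjusted p = 7.87e-05), the matrix protein FBLN2 13.9-fold (9.7e-05) and the membrane-bound BASP1 9.43-fold (1.39e-05). The glycosyltransferase GALNT14 kept 2 of its RNA counts against 46 in controls (ratio 0.0346, 0.00407 to 0.132) and 1 of its footprint counts against 27 (ratio 0.0108, 0.000265 to 0.0657). The fitted log2 change of MYO10 in RNA was -6.22, and -5.44 without control 2. That of GALNT14 in footprints was -5.67, with -5.06 without control 1 and -6.59 without knockout 2. These rest on few knockout counts and are no bound. The clock transcription factor NPAS2 rose 10.4-fold in RNA (4.94 ± 0.328 to 54.0 ± 17.2 CPM, 9.7e-05) and 3.75-fold in footprints (0.00368).

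Other RNA falls in H1299 were PIK3CG (13.5-fold, edgeR adjusted p = 0.0437), SPECC1 (11.5-fold, 0.0185) and the calcium channel CACNA1A (9.90-fold, 0.0150). RNA rises included the calcium-binding S100A16 (5.93-fold, 0.0237), the receptor VIPR1 (3.99-fold, 0.00208), CHMP6 (3.13-fold, 0.0377), the vitamin D hydroxylase CYP24A1 (2.92-fold, 0.0279), TUBB6 (2.63-fold, 0.0258), MELTF (2.61-fold, 0.0414) and GRAMD1B (2.52-fold, 0.0288). Targets of the integrated stress response were called higher (32 of 35 positive, 0 called, 3 over the list alone, median 0.35, camera adjusted p = 1.55e-05; 0.337 with an estimated correlation), with CHAC1 (1.91 ± 0.42, edgeR adjusted p = 0.0510) and TRIB3 (1.66 ± 0.42, 0.112). Cytosolic ribosomal protein transcripts were called higher for the large (44 of 47 positive, median 0.25, 4.6e-05; RPL36 0.73, RPL27 0.73) and small subunit (30 of 33, 0.26, 0.00133; RPS28 0.64, RPS3A 0.53), each with 0 called and 0 over the list alone. The mitoribosomal large subunit (38 of 49, 0.29, 0.00874, 0 called and 0 over the list alone; MRPL12 0.83, MRPL48 0.74) and histones (46 of 50, 0.31, 0.000111, 0 called and 1 over the list alone; H3C1 2.11, H4C1 1.16) were called higher too. None of these 4 lists was called with an estimated correlation (adjusted p = 0.962 each). Without control 2 the mitoribosome (0.19, 0.109) and histone (0.12, 0.181) lists lost their call. edgeR called 8 genes higher and 40 lower among 10490 (DESeq2 70, limma voom 54, H1299 libraries alone 224). With the number split as a term the balance was 347 higher and 431 lower, and with knockouts summed in pairs 2 higher and 8 lower. Without knockout 2 the fitted log2 changes of PIK3CG and SPECC1 were -5.65 and -7.52. These are no bound, as the remaining knockouts held no reads of SPECC1, and reads of PIK3CG in knockout 1 alone. The count was 12 without control 1, 8 without control 2, 13 without knockout 1, 13 without knockout 3 and 17 without knockout 4. Of the 16 named calls BASP1, FBLN2, MYO10, NPAS2 and SLIT3 held in all 6 fits.

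In H1299 footprints ALCAM, a cell adhesion molecule, fell 11.3-fold (42.6 ± 3.73 to 3.59 ± 1.47 CPM, edgeR adjusted p = 1.4e-05) and FBLN2 10.6-fold (0.000198). S100A16 rose 5.09-fold (19.4 ± 4.54 to 103 ± 15.2 CPM, 1.14e-05), VIPR1 5.02-fold (0.000221), LYSMD2 3.71-fold (0.0323), the kinase WNK4 3.10-fold (0.0205), SPOPL 3.09-fold (0.0283) and the matrix protein EMILIN2 2.69-fold (0.00578). RFPL4A and RFPL4AL1 dropped from 43 counts each to 3 and 1 (ratios 0.0204, 95% counting interval 0.00405 to 0.0638, and 0.0068, 0.000168 to 0.04). This is uncertain for either gene because they are near-identical copies. The fitted log2 change of RFPL4A was -5.30, and -5.99 without knockout 2. That of RFPL4AL1 was -6.32, and -7.335 without knockout 3, and neither is a bound. Cholesterol synthesis was called lower (15 of 24 negative, median -0.32, camera adjusted p = 0.0327; adjusted p = 0.962 with an estimated correlation), with INSIG1, a sterol-regulated inhibitor of the pathway, down 2.26-fold (0.00339); over the list alone 4 were lower and 1 higher. The chemokine CXCL3 fell 2.31-fold (0.0335) as the called member of the NF-kB list (11 of 15 negative, -0.51, 0.0167, 2 over the list alone; adjusted p = 0.879 with an estimated correlation).

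Ribosomal protein genes were called higher in H1299 footprints: the large subunit (39 of 47 positive, 4 over the list alone, median 0.32, camera adjusted p = 3.84e-05), with RPL19 (2.09-fold, edgeR adjusted p = 0.0077) and RPL31 (1.69-fold, 0.0388) called, and the small subunit (28 of 33, 0 called, 4 over the list alone, 0.37, 0.000252; RPS24 0.72, RPS15 0.75). Histones were called higher (45 of 50, 3 over the list alone, 0.29, 6.16e-05), with H4C4 (1.86-fold, 0.0402) and H2AC13 (1.69-fold, 0.0453). The integrated stress response (28 of 36, 0.20, 0.0303; MTHFD2 0.62, NARS1 0.70), ribosome biogenesis (35 of 46, 0.22, 0.0391; RRN3 1.02, UTP18 0.67) and the mitoribosomal large subunit (37 of 48, 0.15, 0.0167; MRPL58 0.80, GADD45GIP1 0.87) were called higher with 0 members called and 0 over the list alone. With an estimated correlation the adjusted p = 0.962 for histones, stress response and biogenesis, 0.953 for the mitoribosome, 0.879 for the large subunit and 0.928 for the small subunit. Without H1299 control 2, 6 of the 9 lists called in these footprints lost their call (NF-kB 0.0772, cholesterol 0.0963, stress response 0.0554, mitoribosome 0.0554, histones 0.109 and biogenesis 0.621). Without control 1, cholesterol (0.0636), stress response (0.126) and mitoribosome (0.064) did. Without knockout 1 cholesterol (0.159) and biogenesis (0.0528) were lost, and without knockout 2 the stress response (0.0883). Without knockout 3 NF-kB (0.0517), cholesterol (0.0749), stress response (0.0726) and biogenesis (0.0982) were lost, and without knockout 4 cholesterol (0.0995), stress response (0.101) and biogenesis (0.0623). With knockouts summed in pairs the stress response (0.05) and biogenesis (0.0533) were lost.

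edgeR called 42 genes higher and 132 lower among 9779 in H1299 footprints (72 higher and 118 lower with library totals as the scaling; DESeq2 189 and limma voom 176 in all). With knockouts summed in pairs it called 11 higher and 79 lower. The log2 change of WNK4 was 2.24 without control 1 (0.0803). The count was 32 without control 1, 29 without control 2, 87 without knockout 1, 270 without knockout 2, 62 without knockout 3 and 64 without knockout 4. Of the 29 calls that the naming rule took, ALCAM, FBLN2, GALNT14, MT-CYB, MT-ND4, MYO10, RFPL4A, RFPL4AL1 and S100A16 held in all 6 of these fits.

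The knockout effect was compared between the lines gene by gene. MYO10 (log2 difference in RNA, A549 minus H1299, 6.31 ± 0.81), SLIT3 (6.03 ± 0.66), GALNT14 (5.56 ± 0.74), BASP1 (3.91 ± 0.38) and SFRP1 (3.58 ± 0.56) had a higher estimate in A549, and NPAS2 a higher one in H1299 (-3.33 ± 0.48). In footprints the differences were 7.59 for MYO10, 6.91 for GALNT14, 3.96 for ALCAM, 2.31 for the ubiquitin-conjugating enzyme UBE2D2, 2.29 for the cytokine TGFB1 and -3.01 for S100A16. Estimates for MYO10 and GALNT14 rest on 0 to 2 knockout counts in H1299 and are no bound. That of MYO10 in RNA was 5.54 without H1299 control 2, and that of GALNT14 in footprints was 7.91 without A549 control 1, 6.24 without A549 control 2 and 7.87 without H1299 knockout 2. COL6A1 was the only gene called in the same direction in both lines, in footprints (H1299 1.92-fold, edgeR adjusted p = 0.0274), against 0.0429 expected of independent lists (Fisher's exact p = 0.0421). In opposite directions 0 genes were called in RNA and 0 in footprints. At an adjusted p under 0.1 it was again 1 gene, against 0.238 expected (Fisher's exact p = 0.213), with 3 in opposite directions. With the number split as a term it was 1 against 0.511 (Fisher's exact p = 0.403), with 17 in opposite directions. That term gave 6 genes of the same and 52 of opposite directions in RNA. Of the 6, 2 were higher against 6.02 expected of independent lists and 4 lower against 4.23, so they are no excess. COL6A1 lost its H1299 footprint call in 5 of the 6 fits with 1 library left out and its A549 call in 3. Across genes the changes in the lines correlated at r = -0.158 in RNA, -0.107 in footprints and -0.0827 in efficiency, while RNA and footprint changes of a line correlated at 0.388 (A549) and 0.495 (H1299). Spearman's rho was -0.227, -0.132, -0.114, 0.295 and 0.473 in that order, and genes are not independent replicates. Of the genes called in RNA and tested in footprints, 33 of 33 in A549 and 45 of 45 in H1299 had a footprint change in the same direction, and 7 and 30 of these were called in footprints too.

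edgeR called a line difference for 25 genes higher in A549 and 3 higher in H1299 in RNA (DESeq2 85, limma voom 35 in all) and for 91 and 10 in footprints (53 and 22 with library totals as the scaling; DESeq2 180, limma voom 58 in all). The counts were 5 in RNA and 66 in footprints with knockouts summed in pairs. Library totals moved the median line difference of all genes from -0.02 to -0.14 in RNA and from -0.03 to -0.16 in footprints. Leaving out A549 control 1, control 2 and knockouts 1 to 4 gave 16, 14, 52, 47, 18 and 18 genes in RNA, and the H1299 libraries in that order 8, 7, 13, 45, 7 and 13. In footprints the count was 30 without A549 control 2, 343 without A549 knockout 1, 43 and 44 without A549 knockouts 3 and 4, 27 without either H1299 control, and 182, 60 and 57 without H1299 knockouts 2, 3 and 4. In RNA the SFRP1 difference was lost without H1299 control 1 (adjusted p = 0.0795) and was 4.46 without A549 control 1, and that of NPAS2 was lost without H1299 control 2 (0.0857), while the other 4 named RNA differences and all 6 in footprints held in the 12 fits with 1 library left out.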

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

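Of the tests that weigh explanations here, the 3 for the mtDNA-encoded genes and the 2 for the large falls in H1299 were chosen only after the result was seen, as were the list tests of the line difference and all 3 patterns themselves.

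The knockout effect on mtDNA-encoded footprints differed between the lines, with a log2 difference (A549 minus H1299) of 4.8 in their share of footprint counts and of 3.73 in the ratio of footprint to RNA share. A split of the libraries by number was tested with genotypes reassigned within its sides (exact permutation p = 0.0123, the smallest of 81 arrangements). Line differences within the sides were 3.63 and 5.97. The test cannot weigh that split, because each side holds a control and a pair of knockouts in every set. A shift shared by all libraries of a side therefore cancels from knockout minus control by design. An effect of a side on knockouts alone was not tested. The arrangements also count both knockouts of a side as separate samples, which they may not be. The level of the mtDNA-encoded RNA is argued against as the whole cause, since the ratio to RNA differed between the lines (exact permutation p = 0.00444). That p was 0.0404 with RNA and footprint libraries not matched by number. With knockouts averaged in pairs it was 0.0556, the smallest of 36 arrangements. Mitochondrial RNA fragments in the footprint libraries cannot be told apart from translation, as the share of MTRNR2L counts moved the same way (0.908% to 2.01% in A549, 2.57% to 0.907% in H1299). A straight line on that share was fitted to the 12 footprint libraries. Over it, the line difference of the mtDNA-encoded share was -0.353 percentage points (exact permutation p = 0.631), against 8.77 without it. The fit had no term for genotype or cell line, so it takes up any group difference common to both shares. The small remainder therefore does not show that fragments account for the difference. The ratio of mtDNA-encoded to MTRNR2L counts did differ (by 2.25, exact permutation p = 0.00889), but a constant part of MTRNR2L counts would make it move too. Clones, medium, fragment size and the capture of mitochondrial ribosomes under cycloheximide stay open as well. So does, as a hypothesis, a line-specific effect of METTL5 loss.

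In all 4 sets of line and kind of library, the separation of control 1 with knockouts 1 and 2 from control 2 with knockouts 3 and 4 ranked first among the 6 possible splits. It took 64.8% of the variance within groups in A549 RNA (highest other split 20.9%), 31.6% in A549 footprints (27.4%), 32.2% in H1299 RNA (25.9%) and 32.1% in H1299 footprints (27%). In H1299 the chi-square per degree of freedom of knockout 1 was lower with knockout 4 (3.94 in RNA and 3.91 in footprints) than with knockout 2 (4.87 and 4.57). In RNA that of knockout 2 with knockout 4 was 3.66. This measure grows with depth, and knockout 4 had the lowest total of the H1299 knockouts in RNA (641979) and footprints (1171261). These lower values may therefore reflect depth. For the first rank of the split, depth is argued against, since after thinning to equal totals the split still ranked first in 4 of 4 sets. A shared batch of the numbers and separate clones or guides with changes of their own cannot be told apart, because control and knockout differences along the split correlated across genes at 0.605 in A549 RNA, past the 0.3 a shared batch needs in all 4 sets, at 0.0945 and 0.0903 in A549 and H1299 footprints, under the 0.1 that separate clones need in all 4, and at 0.212 in H1299 RNA, between them. Fitted as a term, this split gave 285 and 778 called genes in A549 and H1299 RNA, where the other 5 splits gave 14 to 35 and 19 to 25. In footprints it gave 62 and 335, where the others gave 7 to 14 and 100 to 215. Because this split takes the most variance within groups, more calls can follow from that alone and are no separate support for it. No group of the design separates the libraries this way, so no biological explanation was tested.

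Large falls of single genes in H1299, such as MYO10 and GALNT14, were seen in RNA and footprints. Preparation of the footprint libraries is argued against, since the nuclear genes with called footprint falls had a median RNA change of -0.89, with 114 of 121 negative. Its 95% interval of -0.97 to -0.77 runs over genes, which are not independent replicates, and does not measure the spread between libraries. An effect of the knockout common to both lines is argued against for the 33 of 40 genes with called RNA falls and at least 5 CPM in A549. Their median change was 0.10 in A549 RNA (95% interval over genes 0.03 to 0.42) and -1.81 in H1299 RNA. These genes were chosen by their falls in H1299, which can inflate the H1299 median. Growth from few cells that had lost these transcripts may account for the falls. So may an effect of METTL5 loss particular to H1299, and neither was tested.

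Knockout effects on 28 genes in RNA and 101 in footprints differed between the lines by edgeR's test of the difference at an adjusted p under 0.05. The named ones in RNA were MYO10 (log2 difference, A549 minus H1299, 6.31), SLIT3 (6.03), GALNT14 (5.56), BASP1 (3.91), SFRP1 (3.58) and NPAS2 (-3.33). In footprints they were MYO10 (7.59), GALNT14 (6.91), ALCAM (3.96), UBE2D2 (2.31), TGFB1 (2.29) and S100A16 (-3.01). Leaving out 1 library moved MYO10 in RNA to 5.54 (H1299 control 2), SFRP1 to 4.46 (A549 control 1) and GALNT14 in footprints to 7.91, 6.24 and 7.87 (A549 control 1, A549 control 2 and H1299 knockout 2). The RNA differences of SFRP1 and NPAS2 were no longer called without H1299 control 1 (adjusted p = 0.0795) and control 2 (0.0857) respectively.

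Gene lists differed between the lines by camera with its preset correlation, and 0 of these differences held with an estimated correlation. Median line differences in RNA were 1.26 for mtDNA-encoded proteins, -0.451 and -0.417 for the large and small mitoribosomal subunit, and -0.465 and -0.373 for the large and small cytosolic ribosomal subunit. They were -0.145 for cytosolic translation factors, -0.342 for the integrated stress response, 0.598 for ER chaperones, -0.299 for mitochondrial protein import, 0.377 for cholesterol synthesis, -0.717 for histones and 0.884 for mesenchymal markers. In footprints they were 5.38 for mtDNA-encoded proteins, -0.417 and -0.26 for the mitoribosomal and -0.508 and -0.481 for the cytosolic ribosomal subunits in the same order. They were -0.257 for ribosome biogenesis, 0.487 for cholesterol synthesis, 0.83 for NF-kB and cytokine genes and 1.29 for mesenchymal markers. In translational efficiency they were 3.86 for mtDNA-encoded proteins and 0.503 for histones.

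In 11 of 169 groups of 4 knockout libraries, 1 library stood far from the other 3, by a gap, relative to the group's range, above the 95% critical value of Dixon's test. Chance gives about 1 in 20. In RNA these were LRIG1 in A549 (gap 0.838 of the range) and TUBB6 (0.838), RPL27 (0.871), RPL36 (0.855), SPECC1 (1) and PIK3CG (0.835) in H1299. In footprints they were SFRP1 in A549 (0.98) and NPAS2 (0.855), WNK4 (0.833), GALNT14 (1) and RFPL4AL1 (1) in H1299. For GALNT14 and RFPL4AL1 a single count in 1 library, with 0 in the other 3, forces the gap of 1. The rate of 1 in 20 does not apply to them.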

How the results depend on the processing

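The term for the separation of libraries by number, the knockouts summed or averaged in pairs, the ratio test with libraries not matched by number, the comparisons and permutations within its sides, the fits without A549 knockouts 3 and 4 or without A549 control 1 and knockout 1 and the list tests without mtDNA-encoded genes were chosen only after the data were seen. Of 83 called values of named genes, 24 kept their direction and call in every alternative run and 0 reversed in any, and of 33 list calls 0 kept theirs in all and 7 reversed in at least 1. Of 119 uncalled values 71 were called in at least 1 alternative. In A549, simulated log2 changes of 1 were recovered in 42.0% of genes in RNA, 12% in footprints and 2.00% in efficiency. Changes of -1 were recovered in 16.3%, 17.4% and 6.38%. These simulated libraries were independent with the same spread for all genes, unlike the real ones. Fewer libraries or genes enter some fits by construction. Otherwise the cause of these changes was not tested.

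Counts of called genes in A549 (37 in RNA, 11 in footprints, 0 in efficiency), in H1299 (48, 174 and 0) and for the line difference (28, 101 and 0) moved by more than 1.5 times as follows. With no low-count filter they were 115, 93 and 3, 128, 298 and 15, and 190, 260 and 20. With each line fitted alone A549 RNA gave 0, H1299 RNA 224, H1299 footprints 461 and H1299 efficiency 4. DESeq2 gave 42 in A549 footprints and 85, 180 and 9 for the line difference. limma voom gave 21 in A549 footprints and 58 for the footprint line difference. The library name term gave 53 and 1 for the RNA and efficiency line differences. The number split gave 285, 62 and 1 in A549, 778, 335 and 6 in H1299, and 870, 268 and 14 for the line difference. In RNA it gave 6 genes called in both lines in the same direction (0 without it) and 52 in opposite directions (0 without it). Of the 6, 2 were higher against 6.02 expected of independent lists and 4 lower against 4.23. All genes called without that term were called with it in RNA and footprints. Without A549 control 1 and knockout 1, A549 footprints gave 162, H1299 efficiency 3 and the efficiency line difference 4, of which 3 and 3 were mtDNA-encoded. Without A549 knockouts 3 and 4, H1299 efficiency gave 8 and its line difference 5, all mtDNA-encoded. Of gene lists, 0 were called with an estimated correlation and 0 with fry, against 33. With mtDNA-encoded genes left out 21 were called, against 27 other than the mtDNA-encoded list that this removes. With knockouts summed in pairs counts were 3 and 6 in A549 RNA and footprints, 10 and 90 in H1299, and 5 and 66 for the line difference, and the genes called in RNA were all among those called without summing. With knockouts averaged in pairs the METTL5 RNA change (-1.02) and the line differences of the mtDNA-encoded share (4.8 in footprints, 3.73 in the ratio) had an exact p of 0.0556, the smallest of 36 arrangements, so this design cannot pass.

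With 1 library left out in turn, counts ran from 3 to 47 in A549 RNA, 8 to 60 in H1299 RNA, 1 to 161 in A549 footprints and 29 to 270 in H1299 footprints. Line differences ran from 7 to 52 in RNA, 27 to 343 in footprints and 0 to 11 in efficiency, and list calls from 18 to 44. Efficiency gave 0 to 0 in either line when 1 of its own libraries was left out, and 2 in H1299 without A549 knockout 1, both mtDNA-encoded. Where 1 control remained, its spread was taken from the other groups. The METTL5 change over both lines ran from -1.16 to -0.88 in RNA and from -1.08 to -0.18 in footprints. The change in the mtDNA-encoded share over both lines ran from -0.16 to 0.32 in RNA, -0.83 to -0.23 in footprints and -0.72 to -0.51 in the ratio, and its line difference from 0.59 to 1.55, 4.19 to 5.41 and 3.52 to 3.93.

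By the criterion fixed for this check, the replicate numbers were taken not to pair the samples. Control and knockout libraries of the same number deviated together at over 0.1 in 2 of 8 pairs (r from -0.533 to 0.502). RNA and footprint libraries did so in 7 of 12 (0.0104 to 0.309). All of these 12 were positive, so a pairing of RNA and footprint libraries is not excluded. The deviations of 2 controls from their mean are opposite by construction, so correlations that use them are not separate checks. The counts with the block had been seen before this check was made, and its criterion was then applied as fixed. With the replicate block, counts were 23, 199 and 96 in A549 RNA, H1299 RNA and their difference, 61 in H1299 footprints, and 4, 14 and 18 in efficiency, of which 4, 13 and 13 were mtDNA-encoded (higher in A549, lower in H1299). The line differences of the mtDNA-encoded share were 4.26 in footprints and 3.60 in the ratio with it (exact p = 0.125, the smallest of 16 arrangements). Within the sides of the number split they were 3.63 and 5.97 in footprints and 3.27 and 4.19 in the ratio (exact p = 0.111, the smallest of 9), so these designs cannot pass the threshold. Genotypes were also reassigned within these sides over both. The line differences of 1.07 in RNA, 4.8 in footprints and 3.73 in the ratio then had an exact permutation p of 0.0123. This is the smallest of 81 arrangements, and for RNA the p was 0.133 otherwise. These arrangements count both knockouts of a side as separate samples, which they may not be.

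Medians of lists that reversed were those of the large ribosomal subunit in A549 RNA (0.0296 with the block, 0.216 without control 1, 0.119 without knockouts 3 and 4, 0.0912 without control 1 and knockout 1), A549 RNA histones (0.159 without control 1, 0.141 without knockouts 3 and 4) and ER chaperones (-0.0176 without knockouts 3 and 4). In H1299 RNA the mtDNA-encoded list had 0.122 without control 2. In A549 footprints the large ribosomal subunit had 0.0736 without control 1 and 0.0377 without control 1 and knockout 1, and the small subunit 0.0205 and 0.0456. In A549 efficiency nuclear complex I had -0.0105 without control 1. The far ends of these lists' ranges with 1 library left out were -0.415 (large subunit) and -0.788 (histones) in A549 RNA, -0.872 in H1299 RNA, -0.248 and -0.303 for the large and small subunit in A549 footprints, and 0.537 for complex I.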

Other observations

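The genes singled out here were chosen after their values were seen, and no explanation was tested. A few genes took a large part of the A549 footprint counts. SHF, an adaptor protein gene, held 3.38% ± 1.07 (SD, n = 2) of them in controls and 2.94% ± 2.42 (n = 4) in knockouts, against 0.546% ± 0.115 and 0.925% ± 0.337 in H1299 footprints. In RNA its share was 0.537% ± 0.258 and 0.510% ± 0.312 in A549, and 0.344% ± 0.0567 and 0.728% ± 0.112 in H1299. The unnamed gene ENSG00000277475 held 2.06% ± 1.11 and 1.33% ± 1.49 of A549 footprint counts, and 0.0968% ± 0.0405 and 0.455% ± 0.268 in H1299. The 10 most counted genes of a library held 10.6% ± 0.380 and 10.9% ± 1.84 in A549 footprints, and 7.85% ± 2.67 and 5.71% ± 0.698 in H1299 footprints. In RNA they held 8.855% ± 0.131 and 12.9% ± 5.01 in A549, and 12.9% ± 6.14 and 9.30% ± 1.02 in H1299. A share of this size in the 10 most counted genes is thus not particular to A549 footprints, but those genes may differ between sets. It does not bear on SHF and ENSG00000277475. Their group means were higher in A549 than in H1299 footprints, though single knockout libraries overlapped.

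Of the 35 lists tested, 21 were not called by camera in any of the 6 comparisons, with medians between -0.37 and 0.37. The smallest adjusted p was 0.0559 for cytosolic translation factors, 0.0967 for fatty acid synthesis, 0.0984 for the mitoribosomal small subunit, 0.103 for mitochondrial protein import, 0.105 for mitosis, 0.128 for nuclear complexes II to IV and 0.13 for fatty acid oxidation. It was 0.174 for mitochondrial chaperones and proteases, 0.191 for MYC targets, 0.237 for mtDNA expression and maintenance, 0.248 for DNA replication, 0.371 for apoptosis regulators, 0.39 for hypoxia targets, 0.397 for nuclear ATP synthase and 0.397 for m6A methyltransferases. It was 0.476 for the tricarboxylic acid cycle, 0.574 for interferon-stimulated genes, 0.61 for glycolysis, 0.634 for p53 targets, 0.639 for mitochondrial translation factors and tRNA synthetases, and 0.663 for neuroendocrine and neuronal markers. A p above the threshold does not show that these groups did not change.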
